A study of Homo sapiens with 2 samples.

How the data were processed

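RNA sequencing was done on 2 cultures of Cal-27, an established cell line from a squamous cell carcinoma of the tongue. One culture carried a scrambled control shRNA and the other an shRNA against HIPK2, both as stably transduced constructs, per the labels' protocols. Total RNA was extracted with TRIzol, libraries were made with a Gnomegen kit and sequenced as paired-end reads of 150 bp on an Illumina HiSeq, per the labels' protocols. Whether the kit marks strand, and whether RNA was selected by poly(A) tail, is not given in the sources used here. Each group held 1 library, so no spread between cultures could be estimated.

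Reads were checked with FastQC and aligned with TopHat2 2.1.1 on GRCh38 (hg38), per the submitters' processing notes. The tool that counted reads, its annotation and its treatment of strand and of reads with several matches are not given in the sources used here. Each deposited table lists 20263 genes by Ensembl ID, name and position. Per the file headers, the authors gave a count, a TPM and an FPKM for each gene. The deposited counts are whole numbers per gene and were not normalized. The deposited TPM sums to 999991.3 and 999989.3 in the libraries and the deposited FPKM is a constant multiple of it within a library. For genes with 1 annotated transcript the count divided by the FPKM followed transcript length, and for other genes it varied between the libraries. Count and TPM of such genes are therefore linked by a length that differs between the libraries. Whether the counts also depend on how reads were assigned to transcripts is not known, because the counting tool is not given. FPKM was used only for the transcript length that it implies.

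The total count was 28064923 in the control library and 26450251 in the library labelled HIPK2 shRNA. The 13 mitochondrial genes took 10.2% and 9.77% of the counts, and the 10 genes with most counts took 12.0% and 12.1%. The files had 27 gene symbols turned into dates, which were restored by gene ID where a symbol was known. Of the 20263 IDs, 20148 matched the symbol table and 20224 matched GENCODE 29, of which 19722 genes were protein coding. Start and end were identical to GENCODE 29 for 80.7% of the matched genes, so positions are given as in the files.

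Counts were converted to CPM, the usual depth-scaled unit, with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.977 and 1.02). No edgeR test was run, because 1 library per group leaves no residual degrees of freedom. A gene was called expressed at 1 CPM or more in at least 1 library. The log2 ratio is log2 of (CPM + 1) in the library labelled HIPK2 shRNA over (CPM + 1) in the control, which understates the ratio of low genes. A gene was called past 2-fold at a log2 ratio of at least 1 or at most -1, which is a rule of size and not a test. Ratios of CPM without the pseudocount are printed with 95% exact (Clopper-Pearson) intervals, conditional on the sum of both counts, from scipy 1.17.1. Levels of the HIPK genes carry exact Poisson intervals. These intervals and limits cover counting error only, and reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts (0.109 CPM in the control and 0.111 CPM in the other library), and no fold is printed for such a gene.

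The gene lists (42), the rule of size, the named genes and most alternatives were fixed before the data were examined. For each of the 35 lists with at least 5 expressed members, the median log2 ratio was set against 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression. A list is said to stand apart when its median lies below the 2.5th or above the 97.5th percentile. Random genes vary independently while members of a list often vary together, so this describes these 2 libraries and is not a p-value. About 1.8 of the 35 lists would stand apart by chance if their members were independent. The named genes are the HIPK family, the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio among genes at 5 CPM or more in a library, and up to 4 members of each list with the largest absolute log2 ratio. Some of the genes this rule names are not reported here.

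The rule of size and the list comparison were tested on simulated counts, over all 20263 genes and with counting noise alone. The counts were simulated for the comparison of the library labelled HIPK2 shRNA with the control. Both simulated libraries came from the mean profile of the real libraries and were scaled by the real totals, without TMM. The scaling step was thus not tested. The 200 genes simulated with a change, 50 per fold size, were drawn from genes at a mean of 5 CPM or more. Of these, 100.0% at 2.5-fold, 3-fold and 4-fold and 0.0% at 1.5-fold were called past 2-fold. Changes in genes of lower level, whose ratios the pseudocount understates, were not simulated. Of 11407 unchanged genes, 0 were called, but no spread between cultures was simulated, so this gives no rate of false calls in the real libraries. A list of 25 genes at 5 CPM or more, lowered by 0.5, came out at -0.52 (log2), and 5 of 100 random lists stood apart.

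Genes that share exons on the same strand were found with GENCODE 29 exons, and their counts were also summed per locus. Log2 ratios were also corrected with 2 rounds of lowess (statsmodels 0.14.6, fraction 0.3) on the length and GC content of the longest transcript, for 11808 of 11813 expressed genes. The other alternatives were pseudocounts of 0.1 and 5 CPM, median-of-ratios and upper-quartile scaling, no filter, a filter at 10 CPM, thresholds of 1.5-fold and 4-fold, protein-coding genes only, the mean in place of the median, and the deposited TPM in place of the counts. The list of nuclear and small structured RNAs had 0 members in the tables, which hold nearly only protein-coding genes.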

Results

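Gene expression was measured in Cal-27 cells, an oral squamous cell carcinoma line, carrying a control shRNA or an shRNA against HIPK2, a nuclear serine/threonine kinase. The comparison asks which genes and pathways, among them those of invasion and of epithelial-mesenchymal transition (EMT), differ after attenuation of HIPK2. Each group had 1 library, with 28064923 counts in the control and 26450251 counts in the library labelled HIPK2 shRNA. No difference below therefore has a replicate check, no p-value is given, and each value compares these libraries and not the conditions. Intervals in brackets are 95% counting intervals.

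The target gene did not show a uniform decrease. HIPK2 (ENSG00000064393, chromosome 7, 139561570 to 139777778, minus strand, GRCh38) had 110 counts in the control and 218 counts in the library labelled HIPK2 shRNA. Its level was 4.01 CPM (3.30 to 4.84) and 8.06 CPM (7.03 to 9.21), a ratio of 2.01 (1.59 to 2.55). In the authors' deposited TPM the same gene went from 1.63 to 0.873, a ratio of 0.537. The paralogs were higher in that library in both units: HIPK3 had a CPM ratio of 1.82 (1.55 to 2.15) and HIPK1 a ratio of 1.34 (1.18 to 1.53), while HIPK4 had 2 counts in each library. Because the counts of the targeted gene go against the label and its TPM goes with it, the sample is called the library labelled HIPK2 shRNA throughout.

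**Figure D1:**
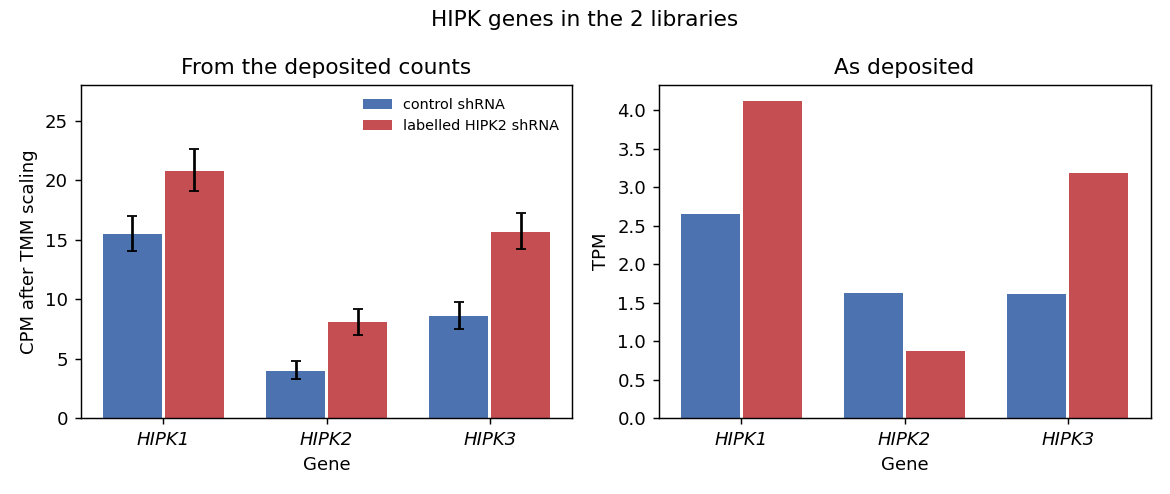
Levels of HIPK1, HIPK2 and HIPK3 in the control library (blue) and the library labelled HIPK2 shRNA (red), as CPM from the counts (left, bars with 95% counting intervals) and as deposited TPM (right, no interval because TPM keeps no depth). HIPK2 stood at 4.01 and 8.06 CPM but at 1.63 and 0.873 TPM.

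Of 11813 expressed genes, 385 were at least 2-fold higher and 339 at least 2-fold lower in the library labelled HIPK2 shRNA, together 6.13% of expressed genes. The median log2 ratio was 0.0 and 9383 genes differed by less than 1.5-fold. Among the highest ratios, PODXL2, a sialomucin of the podocalyxin family, had 6 counts in the control and 1839 in the other library. GNA12, a G protein alpha subunit, went from 28.5 to 290.1 CPM, 10.2 times higher (9.44 to 11). NTN1, the guidance cue netrin-1, was 21.7 times higher (14.5 to 33.8). The receptor phosphatase gene PTPRS was 44.4 times higher (22.3 to 104), from 8 counts. The adhesion receptor ADGRL1 was 17.6 times higher (12 to 26.8), the potassium channel subunit KCNG1 66.7 times (25.7 to 246), from 4 counts, and CYB561D1 11.7 times (9.39 to 14.7). GALNT14, an enzyme of mucin-type glycosylation, had 0 counts in the control, which allows up to 0.109 CPM, and 307 counts in the other library (11.3 CPM).

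Among the lowest ratios, HCLS1, a cortactin-like protein best known from blood cells, was 22.8-fold lower (16.4 to 32.7) in the library labelled HIPK2 shRNA. ALOX5AP, which takes part in leukotriene synthesis, was 47.7-fold lower (24.9 to 105). The antimicrobial genes RNASE7 (147 to 17.8 CPM) and DEFB4A (424 to 29 counts, with a near-identical copy elsewhere in the genome) were 8.29-fold and 14.4-fold lower. The cell adhesion gene MCAM was 9.64-fold lower (8.42 to 11.1), the actin cross-linker FLNC 9.02-fold (7.69 to 10.6), the lipase MGLL 8.81-fold (7.49 to 10.4) and TUSC1 12.2-fold (9.02 to 17). The other 8 of the 24 extreme genes share exons with a neighbour: BUB1B-PAK6, C15orf38-AP3S2, INO80B-WBP1, IRGQ, AC020915.6, BLOC1S5-TXNDC5, ISY1-RAB43 and BCL2L2. Reads in shared exons can be counted for either gene, so these 8 values are uncertain. The summed counts of each locus differed by less than 2-fold, which an abundant neighbour alone can give.

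For EMT, E-cadherin and vimentin differed in opposite directions while most junction genes differed little. CDH1, the epithelial cadherin, was 2.11-fold lower (2.01 to 2.22) in the library labelled HIPK2 shRNA, at 184 and 87.3 CPM. In TPM the log2 ratio of CDH1 was -0.80, which is under 2-fold. VIM was 4.11 times higher (2.43 to 7.32), from 18 to 73 counts, and reached only 2.70 CPM. SNAI1, a repressor of CDH1, was 3.53 times higher (2.51 to 5.05) and its relative SNAI2 was 1.66-fold lower (1.44 to 1.91). Of 34 expressed epithelial junction genes, 32 differed by less than 2-fold. The tight junction gene TJP3 was 3.44 times higher (2.56 to 4.68), against the direction of CDH1, and the list median was 0.023, at percentile 74.5 of matched random lists. Of 19 mesenchymal genes, 10 were higher and 9 lower, and only VIM passed 2-fold. Their median log2 ratio of 0.32 lay at percentile 99.8, with COL5A1 at 0.91, TNC at 0.90 and THBS1 at -0.81. Corrected for transcript length and GC content the median was 0.079, at percentile 77.9, and with no filter on low genes it was -0.029, so in both settings the list no longer stood apart. The 6 expressed EMT transcription factors had a median of 0.27, at percentile 82.5, with SOX9 at 0.36 and SNAI3 at 0.37.

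Invasion genes were mixed. MMP13, a collagenase, was 15.5 times higher (8.21 to 33.0) in the library labelled HIPK2 shRNA, from 10 to 153 counts, and the collagenase MMP1 was 3.75 times higher (2.93 to 4.84). The sheddase ADAM8 was 4.38-fold lower (4.06 to 4.73) and ADAMTS1 2.93-fold lower (2.52 to 3.41). Of 21 expressed matrix protease and inhibitor genes, 4 were past 2-fold higher and 5 past 2-fold lower. The list median of 0.26 lay at percentile 97.6, close to the limit, and at 67.4 after the length and GC correction (median 0.43 in TPM). In the plasminogen activator system 6 of 8 genes were lower, among them the urokinase receptor PLAUR by 1.60-fold (1.48 to 1.74). The list median was -0.28, at percentile 6.60. LAMA5, a laminin alpha chain, was 2.07 times higher (2.0 to 2.14). The basement membrane list as a whole had a median of 0.22 at percentile 99.7, which became -0.12 at percentile 18.2 after the correction. Integrins had a median of -0.078 at percentile 29.3, with ITGB2, also on the leukocyte marker list, at -1.20, ITGB8 at 1.09 and ITGA6, the hemidesmosome subunit, at -0.89.

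**Figure D2:**
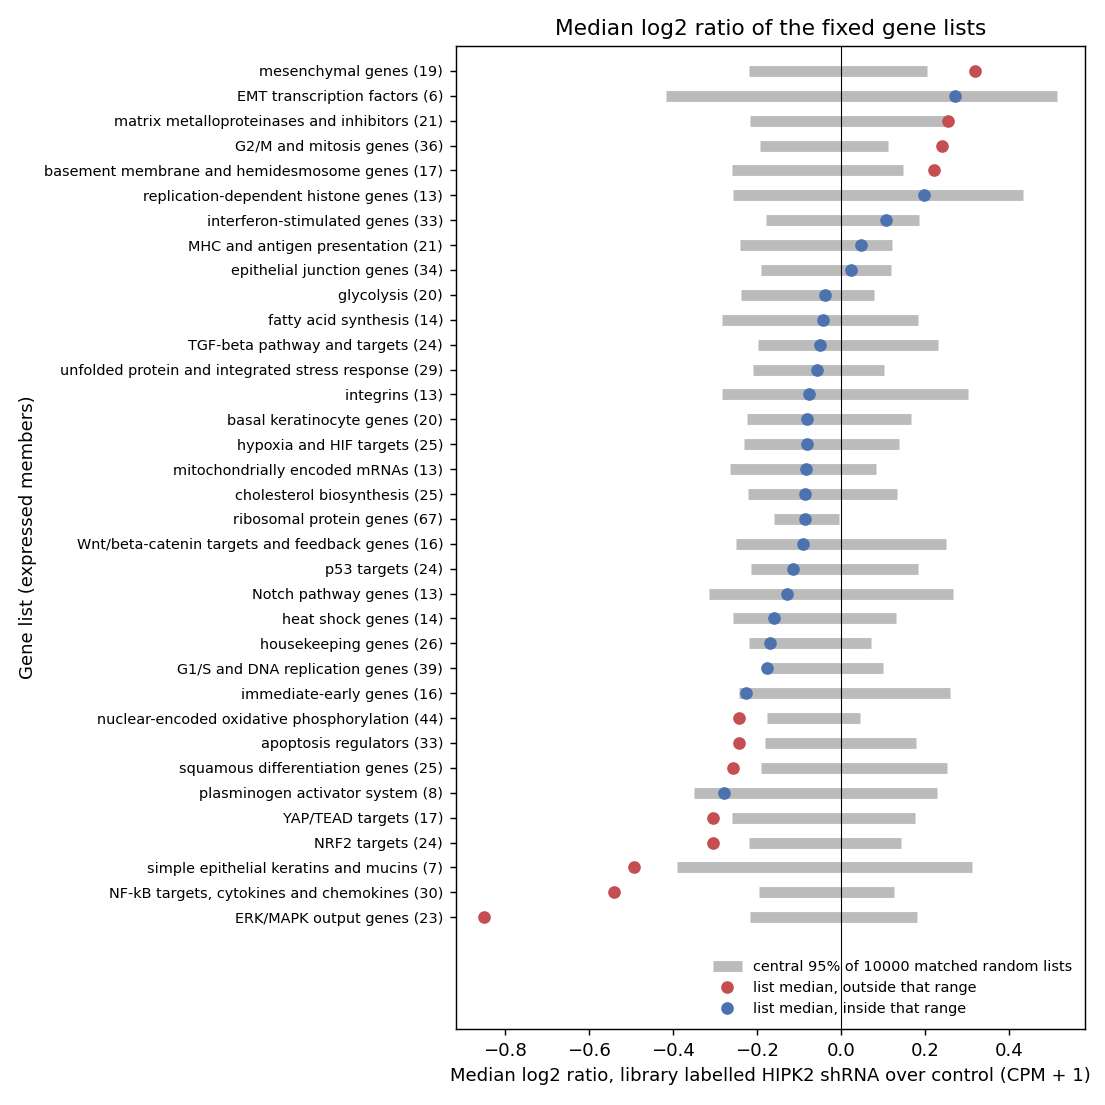
Median log2 ratio (x axis, CPM + 1) of each of the 35 fixed gene lists (y axis, expressed members in brackets), as points over the central 95% of 10000 random lists matched on expression (grey bars). Red points lie outside their bar, led by the ERK/MAPK output genes at -0.85 and the NF-kB list at -0.54.

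The ERK/MAPK output and NF-kB lists had the lowest medians of the 35 lists. Of 23 expressed ERK/MAPK output genes, 20 were lower in the library labelled HIPK2 shRNA and 6 passed 2-fold. In that library HIPK2 was higher in counts and lower in TPM, so a decrease of HIPK2 was not established. The EGF receptor ligands HBEGF and TGFA were 3.24-fold (2.91 to 3.60) and 2.36-fold (2.1 to 2.65) lower. The ERK phosphatase DUSP6 was 2.86-fold lower (2.35 to 3.50) and the ETS factor ETV4 2.23-fold (2.06 to 2.43). The list median was -0.85, and 0 of 10000 matched random lists had a lower one. It was smaller in TPM (-0.55) and with a pseudocount of 5 CPM (-0.52). Of 30 NF-kB targets, cytokines and chemokines, 22 were lower and 9 passed 2-fold, with a median of -0.54 that was also below the random lists (0 of 10000 lower). LCN2, an iron-binding defence protein, went from 726 to 139 CPM, 5.22-fold lower (5.04 to 5.41). IL1A was 4.64-fold lower (4.26 to 5.06), IL1B 3.59-fold (3.42 to 3.78) and CSF2, the gene of GM-CSF, 4.32-fold (4.04 to 4.62).

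Of 17 expressed YAP/TEAD targets, 12 were lower in the library labelled HIPK2 shRNA and 5 passed 2-fold. ANKRD1 had 226 and 7 counts, 31.8-fold lower (15.2 to 80.1). The matricellular genes CTGF and CYR61 were 4.21-fold (3.51 to 5.09) and 2.97-fold (2.90 to 3.04) lower, and the tissue factor gene F3 was 3.05-fold lower (2.94 to 3.17). The list median was -0.30, at percentile 0.94. It no longer stood apart in TPM (-0.13, percentile 6.36) or with a filter at 10 CPM (percentile 2.65), and its mean was -0.54. In the Notch pathway, NOTCH3 was 6.06 times higher (5.26 to 6.99) and the Notch target HEYL went from 3 to 82 counts, 27.7 times higher (9.15 to 137). The list of 13 Notch genes did not stand apart (median -0.13 at percentile 23.8, mean 0.28 at percentile 97.4, just inside the upper limit), with HES2 at -0.90 and NOTCH1 at 0.72. In the TGF-beta list of 24 genes, 2 were past 2-fold higher and 3 lower (median -0.050, percentile 25.5; median 0.016 under upper-quartile scaling). BMP7 was 6.55 times higher (4.24 to 10.5), and TGFB1 and LTBP2 were 2.28-fold (2.11 to 2.47) and 2.78-fold (2.42 to 3.21) lower. Of 16 Wnt targets and feedback genes, 11 were lower (median -0.090 at percentile 23.2, mean 0.071 at percentile 66.6). NKD1, an inhibitor of Wnt signalling, had 8 and 77 counts and LEF1 4 and 38, while DKK3 was 2.04-fold lower (1.90 to 2.18).

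**Figure D3:**
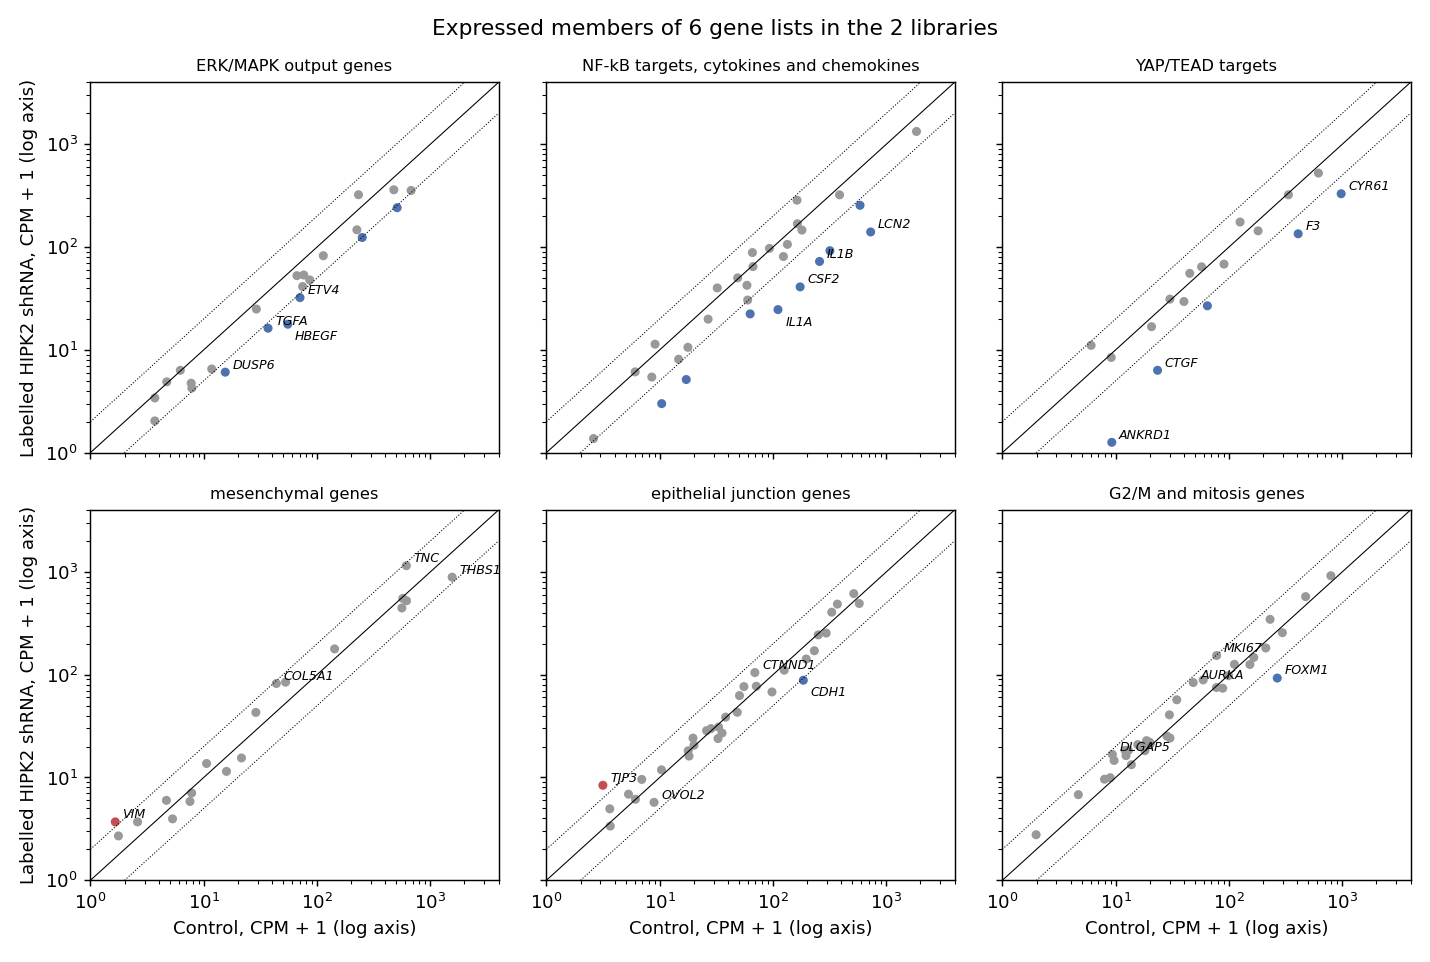
Expressed members of 6 gene lists by CPM + 1 in the control (x axis) and in the library labelled HIPK2 shRNA (y axis), both on log axes, with equality solid, 2-fold dotted, points past 2-fold higher in red and lower in blue, and the 4 members with the largest absolute log2 ratio named. For the ERK/MAPK list 20 of 23 points lie below the line, and for the G2/M list 25 of 36 lie above it.

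Mitotic genes were mostly higher and genes of squamous differentiation mostly lower in the library labelled HIPK2 shRNA. Of 36 G2/M genes, 25 were higher, with a median of 0.24 above 10000 of the 10000 random lists. The proliferation marker MKI67 was 1.99 times higher (1.88 to 2.09), DLGAP5 1.89 times (1.60 to 2.22) and the mitotic kinase AURKA 1.75 times (1.63 to 1.87). FOXM1, a transcription factor that activates mitotic genes, went the other way, at 266 and 91.7 CPM, 2.90-fold lower (2.77 to 3.03), and was the single member past 2-fold, with exons that overlap a gene on the opposite strand. Of 39 G1/S genes 25 were lower (median -0.18, percentile 2.69, but -0.052 at 36.8 after the length and GC correction and -0.074 at 5.89 in TPM), with GINS4 at -1.61, CDC6 at -0.79 and CCNE2 at 1.02. Of 25 expressed squamous differentiation genes, 16 were lower and 9 higher, with 4 past 2-fold lower and 1 past 2-fold higher. Their median was -0.26 (percentile 0.48, and 9.98 with a filter at 10 CPM). That median was -0.15 with no filter and -0.44 in TPM. SPRR2D, of the cornified envelope and with near-identical relatives that can exchange reads, had 177 and 15 counts, and S100A7, S100A8 and S100A9 were 6.31-fold (4.67 to 8.69), 3.65-fold (2.56 to 5.31) and 2.67-fold (2.54 to 2.81) lower. Of 20 basal keratinocyte genes, KRT14 was 7.13-fold lower (5.19 to 10.0) and the adhesion receptor CD44 2.04-fold lower (1.99 to 2.1), with a list median of -0.080 at percentile 28.2. Among 7 simple epithelial keratins and mucins, KRT7 was 2.51-fold lower (2.31 to 2.72) and MUC20 2.26-fold (1.87 to 2.73), with a median of -0.49 at percentile 0.79 (3.27 for the mean).

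HIPK2 is known to phosphorylate p53. The 24 p53 targets had a median of -0.11 at percentile 15.1, with CCNG1 2.92-fold lower (2.36 to 3.65) and FDXR 2.19 times higher (2.03 to 2.36). In TPM CCNG1 had a log2 ratio of -0.65, which is under 2-fold, and FDXR one of 1.18. The 25 hypoxia and HIF targets had a median of -0.080 at percentile 33.1. In that list VEGFA was 4.32-fold lower (3.89 to 4.81) and STC2 2.56-fold lower (2.42 to 2.72), while ENO2 and ALDOC had log2 ratios of 0.95 and 0.88. Of 24 NRF2 targets 19 were lower in the library labelled HIPK2 shRNA (median -0.31, percentile 0.16, and -0.20 after the length and GC correction). AKR1C1, AKR1C2 and AKR1C3 had log2 ratios of -1.50, -0.95 and -0.98, but these near-identical genes can exchange reads. Of 33 apoptosis regulators 23 were lower (median -0.24, percentile 0.37), and 4.10 was the percentile after the length and GC correction. That median was -0.12 in TPM, -0.13 with a pseudocount of 5 CPM and -0.39 with a filter at 10 CPM. Those past 2-fold included the TRAIL receptors TNFRSF10D, 2.81-fold lower (2.39 to 3.31), and TNFRSF10A, 2.24-fold lower (2.0 to 2.52). BIK, a pro-death BCL2 relative, was 2.07-fold lower (1.91 to 2.25) and the survival gene BCL2A1 had 67 and 13 counts.

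Some named genes overlap exons of a gene on the opposite strand, so that reads could be exchanged if counting ignored strand: HIPK4, BCL2L2, MCAM, TNC, THBS1, LAMA5, TGFB1, ETV4, FOXM1 and CCNE2.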

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

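With 1 library per group no replicate could be left out, and no paired analysis was possible because each group holds a single library. The corrections for transcript length and GC content and the handling of genes sharing exons were chosen after the data were seen. The counts of 385 higher and 339 lower genes became 676 and 515 with a pseudocount of 0.1, 124 and 161 with one of 5, and 159 and 217 with a filter at 10 CPM. They were 1254 and 1176 at 1.5-fold and 62 and 48 at 4-fold. Under the other scalings, TPM, the correction and summed loci each count stayed within 1.5 times, with 338 and 294 for summed loci. Dropping the filter could not change the counts, since the pseudocount keeps a gene under 1 CPM in both libraries below 2-fold. Protein-coding genes alone gave 384 and 338, but nearly all listed genes are of that type. The log2 ratio of HIPK2, 0.85, was 0.54 with a pseudocount of 5 and -0.49 in TPM, which reverses it. Of 348 list medians under other settings, 321 kept their side of the percentile limits, 16 came inside them, 9 came outside them, and 2 that had stood apart changed sign. Of lists inside the limits, the TGF-beta, unfolded protein, fatty acid and glycolysis medians also changed sign with upper-quartile scaling (to 0.016, 0.013, 0.027 and 0.034), and several more near 0 did so in TPM. The ERK/MAPK, NF-kB, G2/M and NRF2 lists stood apart the same way under the 10 other settings tried, the ERK/MAPK median ranging from -0.86 to -0.52. The mesenchymal list was -0.029 with no filter, 0.135 at 10 CPM, 0.246 in TPM, 0.079 when corrected and 0.16 as a mean. The protease list was 0.26 with a pseudocount of 0.1 and without genes sharing exons, 0.115 with no filter, 0.064 when corrected and 0.12 as a mean. The basement membrane list was 0.25 in TPM and -0.12 when corrected, and the YAP/TEAD list -0.30 at 10 CPM (percentile 2.65) and -0.13 in TPM. Inside the limits came also squamous differentiation at -0.26 (10 CPM), oxidative phosphorylation at -0.087 and apoptosis regulators at -0.14 (both corrected), and simple keratins at -0.37 (mean). Outside them came G1/S at -0.17 (pseudocount 5) and -0.23 (10 CPM), immediate-early genes at -0.22, ribosomal proteins at 0.11 and mitochondrial mRNAs at 0.21 (all corrected), and mitochondrial mRNAs at -0.36 (without genes sharing exons). As means, MHC genes at 0.17, basal keratinocyte genes at -0.27 and housekeeping genes at -0.23 did so too. Apart from lists left with fewer genes by a filter, the cause was not tested. Depth limits the low genes: 1 count is worth 0.0365 CPM in the control and 0.037 CPM in the other library.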

Other observations

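The tests of the HIPK2 discordance, the tests of genes sharing exons and the correction for transcript length and GC content were chosen after results were seen. Lipid synthesis genes divided. SCD, the stearoyl-CoA desaturase, was 2.59 times higher (2.51 to 2.67) in the library labelled HIPK2 shRNA, its regulator SREBF1, which overlaps a gene on the opposite strand, 2.37 times (2.29 to 2.46) and FASN 1.67 times (1.63 to 1.71). The 14 fatty acid genes had a median of -0.043 at percentile 48.2 and a mean of 0.10 at percentile 88.4, with ELOVL1 at -0.70. The 25 cholesterol genes had a median of -0.086 at percentile 28.8, with HMGCS1 at -0.73. Of 44 nuclear-encoded respiratory chain genes 37 were lower (median -0.24, percentile 0.19), among them COX7C by 2.14-fold (2.05 to 2.23), but the median was -0.14 in TPM and the corrected one was -0.087 at percentile 18.8. Glycolysis genes had a median of -0.038 at percentile 65.5, with ENO2 at 0.95, ALDOC at 0.88 and LDHB at -0.79. MT-ND6 was at -0.83, and the 13 mitochondrial mRNAs had a median of -0.084 at percentile 46.1. The direction of that median depended on the setting. It was 0.21 (percentile 99.8) after the length and GC correction and -0.36 (percentile 1.2) without genes sharing exons.

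Unlike the NF-kB and NRF2 lists, the following stress and immune lists did not stand apart. Interferon-stimulated genes had a median of 0.11 (percentile 87.7, BST2 at -1.15) and MHC genes 0.048 (87.4, HLA-DPB1 at 1.33). Heat shock genes had -0.16 (14.6, HSP90AA1 at 0.77) and the unfolded protein and integrated stress list -0.058 (43.7, VLDLR at -1.77). HLA-DPB1 and HSP90AA1 also overlap genes on the opposite strand. Ribosomal protein genes had a median of -0.086 (38.4), histone genes 0.20 (76.3) and housekeeping genes -0.17 (7.73; VPS29 at -1.23). Markers of other cell types were scarce: 3 of 10 fibroblast, 4 of 16 leukocyte, 2 of 10 endothelial, 0 of 9 erythroid and 3 of 14 muscle and nerve genes were expressed. Of these CDH5, the endothelial cadherin, had 55.2 and 27.3 CPM, 2.02-fold lower (1.85 to 2.21), COL1A1 9.59 and 12.7 CPM, CD68 23.1 and 20.6 CPM, ITGB2 7.14 and 2.55 CPM (the single leukocyte marker past 2-fold), and TNNT1 11.2 and 9.05 CPM.

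HIPK2 was 2.01 times higher in counts and 0.537 times as high in TPM in the library labelled HIPK2 shRNA. Counting noise is argued against, since the interval of the count ratio started at 1.59. The length implied by count and FPKM was 3442 nt in the control and 13819 nt in the other library, 4.01 times longer. Among 10342 genes with 50 or more counts in both libraries, the central 95% of that ratio ran from 0.704 to 1.40. A discordance of this size was thus rare, which does not tell its cause. GENCODE 29 lists HIPK2 transcripts of 2937, 3969 and 15049 nt. Reads assigned to the long transcript in that library are a candidate explanation, but the ratio of lengths restates the difference between counts and TPM, so it cannot decide this, and which transcript was present stays open. An exchange of the 2 libraries cannot be told apart, because the TPM ratio of 0.537 goes with the label and the counts against it, and whether the shRNA lowered HIPK2 cannot be decided from these tables.

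Of 1255 expressed genes that share exons with another gene 112 passed 2-fold, against 77 (61 to 94) in draws matched on level from genes without shared exons. For 89 of the 112 the summed locus was under 2-fold, against 79 (73 to 85) when partner genes were shuffled among loci, so shuffled partners gave most of that number. ISY1-RAB43 had 500 and 0 counts while RAB43 had 70 and 730, as reads given to another gene model in each library could give. C15orf38-AP3S2 had 1 and 1236 while AP3S2 had 1293 and 717, but the summed locus went from 1735 to 2371 counts. A shift of reads between those gene models can cover only part of that gain. Neighbours did not differ in the opposite direction to match at every locus: BLOC1S5-TXNDC5 had 658 and 0 counts while TXNDC5 had 7803 and 6619, and IRGQ had 21 and 740 while XRCC1 had 1369 and 1686 (the neighbours named were chosen after their values were seen). No biological explanation, such as altered read-through transcription, was tested.

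The ERK/MAPK, NF-kB and YAP/TEAD lists share no expressed gene and were each lower in the library labelled HIPK2 shRNA. In that library the HIPK2 counts go against the label and its TPM goes with it. Longer transcripts had higher ratios in general, with a median log2 ratio of -0.14 in the group of shortest transcripts (median 1738 nt) and 0.17 in that of longest (median 7027 nt; Spearman 0.255 across genes, which are not independent replicates). For the ERK/MAPK, NF-kB and YAP/TEAD lists this trend is argued against as the whole cause. After correction 3 of the 3 lists stayed below the 2.5th percentile, with medians of -0.70, -0.42 and -0.31. Some other lists that had stood apart came inside the limits under the same correction, as given above, so this does not extend to them. A different state of the cultures at harvest, such as density or time since feeding, might give the same pattern. It cannot be told apart from the shRNA with 1 library each. The immediate-early list, read as a sign of that state, lay at percentile 3.3 with a median of -0.23. Its percentile was 2.32 after correction, but 28.9 with a filter at 10 CPM and 7.14 with no filter, both with a median of -0.11. That list shares CYR61 with the YAP/TEAD list, and an effect of the shRNA on signalling could lower it too. The immediate-early list therefore cannot decide between the culture state and the shRNA. An effect of the shRNA stays among the open explanations, untested.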
